A study of Homo sapiens with 4 samples.

How the data were processed

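CLIP-seq of RBM15 was carried out in wild-type 22Rv1 cells, a human prostate carcinoma line. Per the labels' protocols, cell lysates were treated with RNase T1, RNA bound by RBM15 was recovered with an antibody, the ends of CLIP and input RNA were repaired with T4 polynucleotide kinase, and libraries were made with a small RNA kit. The labels name 2 CLIP libraries and 2 input libraries. Nothing in them says whether the libraries of a group came from separate cultures.

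Reads were trimmed with cutadapt and aligned with STAR to hg19, per the submitters' processing notes, which give no versions. The peak caller, its threshold, the annotation release and whether replicates were pooled are not given in the sources used here. The deposited table is a single peak list for the series, in which each peak has a position, a strand, a gene identifier with a running number, and a score. The score is the authors' own value per peak, deposited with its highest value at 1000. It has no stated unit. Within the list, it was used to describe, rank and filter peaks, and to compare genes by their strongest, mean or summed score. Ratios of scores hold on the authors' scale only and are not ratios of binding. The score of an interval could also differ with the gene it was listed under. Without pseudoautosomal copies, 557 intervals stood under more than 1 gene of the same strand. Their highest score exceeded the lowest by a median of 18.5%, by more than 2-fold in 12.7% of them, and by up to 35.4-fold. Ranks and comparisons of genes by score can thus reflect the gene as well as the signal in the peak. Positions are hg19 bases per the submitters' processing notes and were deposited with starts counted from 0; they are printed here counted from 1. The running numbers of the peaks had no gap. The list holds no counts, coverage, fold or p-value, so the depth per library and the precision it gives are unknown, and the planned test of CLIP against input per peak was not run.

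RNase T1 cuts after guanine, so peak ends and short peaks can follow the enzyme as well as the protein. How the authors used the input libraries in calling peaks is not given in the sources used here, and a gene without a peak may have been bound below their threshold or not expressed. Expression in these cells was not analysed here. The same interval could be listed under several genes, on the same or on opposite strands: 2634 peaks (16.4%) had an interval also listed under another gene, and 14697 distinct positions remained when strand and gene were ignored.

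The gene column of the list was used as deposited. Of the 9306 gene identifiers, 8971 matched a table of gene names and 9014 matched GENCODE release 29; 292 matched neither and are named by identifier. The annotation is of another genome build than the peak list: 12.2% of peaks fell inside the annotated span of their own gene. It was used for names, gene classes and lengths of mature transcripts and introns, and no position was taken from it or converted. Mature length here is the joint length of all annotated exons of a gene, over all its transcripts. It can exceed the length of any single transcript. Intronic length is the rest of the gene's span. The location of peaks within transcripts and the sequence in peaks, both planned, were not analysed here for want of an hg19 annotation and genome. A list gene was matched by its current symbol, and by an older symbol or synonym only where that identifier lay at the same place in the annotation, as for RN7SK.

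A gene's strength was the score of its strongest peak. Before the data were examined, 14 gene lists were fixed from textbook knowledge, except that FAS, TP53INP1 and SESN2 entered the p53 list through prior knowledge of the study. The lists covered the p53 pathway, the m6A machinery, androgen signalling and the prostate, SR and hnRNP splicing factors, long noncoding RNAs, small structured RNAs, histones, cytosolic ribosomal proteins, the cell cycle, apoptosis, mitochondrially encoded genes, known RBM15 partners and targets, and hematopoietic and stromal markers of other cell types. For each list with at least 3 genes with a peak, the median strength and the mean number of peaks per gene were compared with 100000 random sets of the same size drawn from all genes with a peak, in a two-sided permutation test whose smallest possible p is 2e-05. P-values were adjusted by the Benjamini-Hochberg method over the 10 lists tested, separately for each measure, with a threshold of 0.05. These tests measure the spread between genes, not between replicates, and exact binomial intervals of shares of peaks cover counting error only. Named genes were chosen by a rule fixed in advance: the 15 genes with the strongest peaks, the 10 with the most peaks, the 4 strongest genes with a peak in each list, and always FAS, TP53INP1, SESN2, FTO and RBM15. Some genes that this rule takes in are not reported here. Other genes, such as members without a peak or sharing an interval, were named after their values were seen.

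The permutation tests were tested on simulated lists of 10 and 25 genes drawn from the 9306 genes, with 200 lists per setting. Without an effect, the strength test called 3.5% of lists at either size and the test of peaks per gene 2.5% and 7.0%. With a 2-fold effect, the strength test called 46.5% and 79.5%, and the test of peaks per gene 72.0% and 98.5%. Before correction, a list of about 10 genes thus missed a 2-fold difference in strength about as often as it found it. After correction over the lists, such a difference would be found no more often. For peaks per gene, the simulated effect multiplied the count of every list gene by 2. No simulated list gene therefore had 1 peak, whereas 63.5% of all genes did. A difference carried by only some genes of a list was not simulated.

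The settings varied by that same plan were peaks at or above the median score, merging of peaks of a gene within 50 bases, standard chromosomes only, genes with at least 2 peaks, the mean or sum of a gene's scores, and random sets matched on the number of peaks. Settings added after the data were seen were protein-coding genes as background, matching on mature transcript length, and leaving out or collapsing intervals listed under several genes or on both strands. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.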

Results

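RNA bound by RBM15 was mapped by crosslinking and immunoprecipitation with sequencing (CLIP-seq) in 22Rv1 cells, an established human prostate carcinoma line. RBM15 is an RNA-binding protein that serves as an adaptor of the nuclear complex that writes N6-methyladenosine (m6A) into messenger RNA. The series holds 4 libraries, of which 2 came from immunoprecipitation with an antibody against RBM15 and 2 from input RNA. The data analysed here are a single peak list for the whole series, with 16083 peaks under 9306 genes and a score for each peak that is the authors' own. The list carries no value per library, so depth is unknown, no peak has a replicate error, and each value below is a single value. The study's title concerns m6A inhibition by a long noncoding RNA from the FTO locus and p53 tumor suppression, and the question put to the list was which transcripts carried RBM15 peaks.

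The strongest peak lay in HECTD4, a HECT-domain gene, with a score of 1000, which is the top of the scale, at chromosome 12, 112704952 to 112705120 (hg19). KIF2A, a microtubule-depolymerizing kinesin, followed with a score of 962.6 for its only peak (chromosome 5, 61681351 to 61681400). The forkhead gene FOXN3 had a peak scored 801.5 (chromosome 14, 89634731 to 89634759) and SEC14L1 a peak scored 679.7 (chromosome 17, 75158323 to 75158392). The next scores were 645.8 in BTRC, which encodes a substrate-recognition subunit of a ubiquitin ligase, 626.0 in the zinc transporter gene SLC39A11, 590.6 in the ryanodine receptor gene RYR2 and 558.0 in HSP90AA1, a cytosolic chaperone with 6 peaks. The 15 genes with the strongest peaks also included NOTCH2 at 505.8, PKP4 at 505.1, SSH1 at 488.4, CTNNA3 at 481.4, SCAPER at 433.5, and the unnamed gene ENSG00000255168 at 506.1, whose interval was listed under 2 genes. Whether these peaks lay in exons or introns was not analysed here. The strongest peaks of FOXN3, PKP4 and SSH1 were 29, 27 and 25 bases long, and peaks this short can follow the RNase as well as RBM15.

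Ranked by the number of peaks instead, AHNAK, which encodes a very large scaffold protein, came first with 25 peaks and a strongest score of 171.0. SNHG14, the long host transcript of imprinted small nucleolar RNAs, had 22 peaks, with a strongest score of only 31.2. PRKDC, the catalytic subunit of DNA-dependent protein kinase, had 18 peaks, SMARCA4, the ATPase of the SWI/SNF chromatin remodeler, had 17, and the dynein heavy chain gene DYNC1H1 and the scaffold gene AKAP9 had 16 each. DNMT1, the maintenance DNA methyltransferase, and the chromatin remodeler gene CHD6 had 15 each. EIF2B5 also had 18 peaks and CAST 16, but 9 of the EIF2B5 intervals were listed under another gene as well, 5 of them under EIF4G1, and 5 of the CAST intervals were listed under ERAP1 too.

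Peak scores were skewed, with a median of 8.19, a 90th percentile of 28.6 and a 99th percentile of 114.4. The 100 strongest peaks held 11.8% of the summed score. Peaks had a median length of 64 bases (interquartile range 45 to 88), and 1947 were shorter than 30 bases. Across peaks, which are not replicates, longer peaks scored higher (Spearman's rho 0.56), a relation that fell to 0.18 among peaks at or above the median score. That filter narrows the range of the score itself, which can by itself lower the correlation. Of the 9306 genes, 5907 (63.5%) had 1 peak, 395 had 5 or more and 35 had 10 or more. Keeping only peaks at or above the median score left 5188 genes, and requiring at least 2 peaks left 3399.

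**Figure D1:**
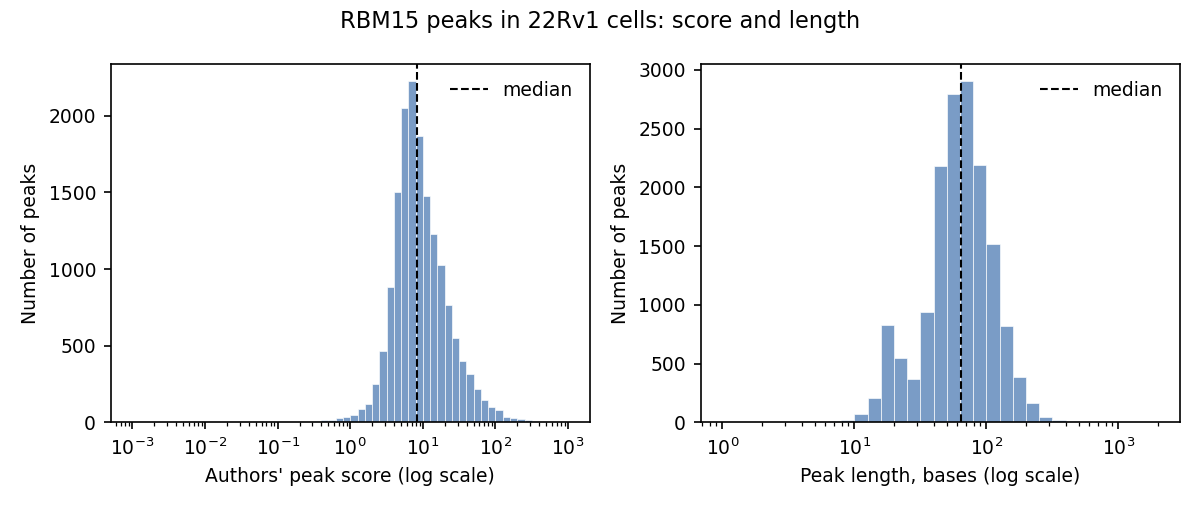
Histograms of the authors' peak score (left) and of peak length in bases (right) for the 16083 RBM15 peaks, both on logarithmic horizontal axes with the number of peaks on the vertical axes. The dashed lines mark the medians, 8.19 for the score and 64 bases for the length.

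Protein-coding genes held 12808 peaks (79.6%), and 6759 of the 19951 protein-coding genes in the annotation (33.9%) had at least 1. Processed pseudogenes held 821 peaks in 721 genes, antisense genes 778 peaks in 578 genes, and long intergenic noncoding genes 428 peaks in 359 genes. The median strongest score was 10.34 in protein-coding genes, 6.84 in processed pseudogenes, 7.6 in antisense genes and 6.71 in long intergenic noncoding genes. Chromosomes 1 and 19 carried the most peaks, 1619 and 1099, but per annotated protein-coding gene they carried 0.79 and 0.75, against 1.05 on chromosome 15, 0.99 on chromosome 7 and 0.97 on chromosome 5. The mitochondrial genome carried 0, so that none of the 15 mitochondrially encoded genes examined had a peak.

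Many intervals stood under more than a single gene, and this limits what the gene column can say. On the same strand, 558 intervals were listed under several genes; the extreme was an interval in the gamma protocadherin cluster (chromosome 5, 140892055 to 140892077), listed under 20 genes that include PCDHGA1 and PCDHGC5. A further overlap ran across strands: 740 intervals appeared with the same start and end under genes of both strands, such as PEBP1 and VSIG10 (scores 119.71 and 380.29) and KIZ and its antisense gene KIZ-AS1 (111.09 and 129.92). The paired scores had a rank correlation of 0.82 across intervals. Such intervals made up 40.9% of the peaks of antisense genes, 13.0% of those of processed pseudogenes and 7.0% of those of protein-coding genes. Among peaks lying between the outermost peaks of a gene on the opposite strand, 356 of 434 (82.0%, exact 95% interval 78.1 to 85.5) overlapped a peak of that gene. For a gene on the same strand, 296 of 351 (84.3%, 80.1 to 88.0) did. Any overlap counted, so the intervals need not be the same. Of the peaks whose gene could be looked up, 99.74% carried the annotated strand of that gene. The listed strand may have been taken from the gene, so this share does not show that reads were separated by strand. Peaks of overlapping, antisense and near-identical genes are uncertain for these reasons.

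**Figure D2:**
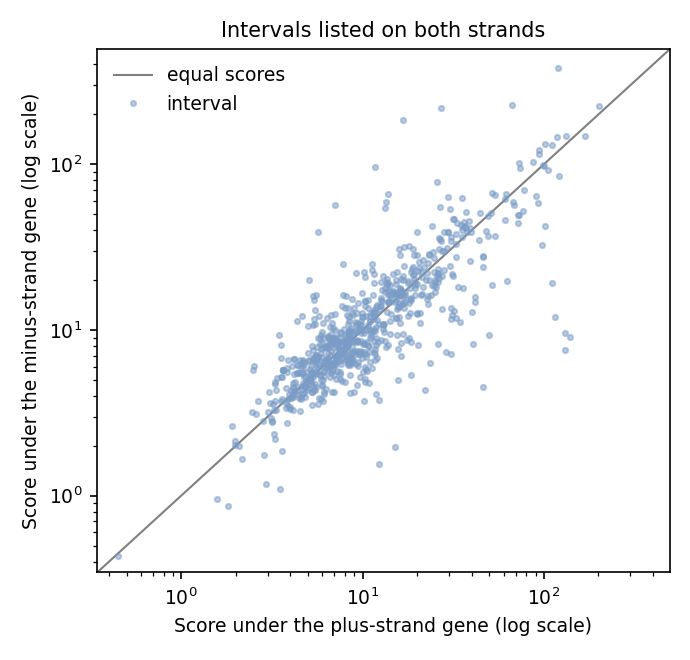
Scores of the 740 intervals listed with the same start and end under genes of both strands; each point is an interval, with its score under the plus-strand gene on the horizontal axis and under the minus-strand gene on the vertical axis, both logarithmic. The points follow the grey line of equal scores (Spearman's rho 0.82), with exceptions such as KALRN at 138.97 and RPL7P15 at 9.01.

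FAS, TP53INP1 and SESN2, which were examined because of prior knowledge of the study's interest in them, had no peak in the list. In the fixed list of 30 p53 pathway genes, 10 had a peak, and 9 of these had exactly 1. The strongest were in the metabolic regulator TIGAR (30.7), the DNA repair genes XPC (19.2) and DDB2 (14.8), and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (11.9). The list's median strongest score was 10.91 (interquartile range 3.76 to 14.07), 1.17 times that of random sets of genes with a peak (two-sided permutation p = 0.653, adjusted p = 0.653). Its mean of 1.1 peaks per gene (SD 0.32 over genes) was 0.64 times the random mean (two-sided permutation p = 0.0877, adjusted p = 0.146). As FAS, TP53INP1 and SESN2 entered the list through that knowledge, they are not independent evidence about it.

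The m6A machinery had peaks in 12 of 21 genes. The highest scores belonged to transcripts of the writer complex's own cofactors, ZC3H13 (113.1, 4 peaks) and VIRMA (88.8, 4 peaks), followed by HNRNPC (69.1), an m6A-sensitive splicing regulator, and the reader and helicase YTHDC2 (39.1). The only peak of YTHDC2 was 17 bases long, short enough to follow the RNase. RBM15 itself had 3 peaks, the strongest scored 22.9 at chromosome 1, 110884502 to 110884594, with the others at 14.3 and 10.3. METTL3, the catalytic subunit, had a peak at 6.38, whereas METTL14 and the demethylases FTO and ALKBH5 had no peak. The list's median of 20.56 (interquartile range 10.76 to 46.58) was 2.21 times the random median and missed the threshold after correction (two-sided permutation p = 0.0239, adjusted p = 0.0598). It passed in 2 of 7 alternative settings, when a gene's peaks were summed (2.78-fold, permutation adjusted p = 0.0278) and when intervals listed on both strands were left out (2.27-fold, permutation adjusted p = 0.0451), and was 1.47-fold against genes with the same number of peaks (permutation adjusted p = 0.326). Its 2.58 peaks per gene (SD 1.51 over genes) were 1.49 times the random mean (two-sided permutation adjusted p = 0.146).

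Splicing factors were the only list to pass both tests. Expression was not used, so neither test, in this or any other list, separates binding from expression. Of 29 genes encoding SR proteins, hnRNPs and their relatives, 25 had a peak, together 89 peaks. HNRNPD (58.5), the polypyrimidine tract-binding protein gene PTBP1 (57.7), SRSF11 (53.9) and SRRM2 (53.8, with 11 peaks) had the strongest. The median of 26.09 (interquartile range 17.35 to 42.95) was 2.82 times the random median, and the mean of 3.56 peaks per gene (SD 2.92 over genes) was 2.06 times the random mean; both had a two-sided permutation p of 4e-05 (adjusted p = 0.0004). Against genes with the same number of peaks, the difference in score was 1.57-fold and no longer passed (permutation adjusted p = 0.185).

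Histone genes with a peak scored high. In the list of 22 histone genes, 13 had a peak, led by H2BC12 (79.7), H2BC5 (71.5) and H2AC6 (59.5). The median of 34.48 (interquartile range 19.1 to 40.27) was 3.73 times the random median (two-sided permutation p = 0.00036, adjusted p = 0.0018), while the mean of 1.23 peaks per gene (SD 0.44 over genes) was 0.71 times the random mean (two-sided permutation adjusted p = 0.203). Histone genes are near-identical copies of each other, so the assignment of a peak to 1 of them is uncertain.

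Genes for cytosolic ribosomal proteins had a peak in 29 of 33 cases, with RPL4 (192.2) and RPL27A (128.7), each with 6 peaks, far above RPLP2 (47.2). Their median of 17.06 (interquartile range 10.7 to 30.9) was 1.85 times the random median (two-sided permutation p = 0.0093, adjusted p = 0.031). The call was lost against protein-coding genes only (1.65-fold, permutation adjusted p = 0.104) and against genes with the same number of peaks (1.36-fold, permutation adjusted p = 0.313). The mean of 2.31 peaks per gene (SD 1.37 over genes) was 1.34 times the random mean (two-sided permutation adjusted p = 0.146).

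Known RBM15 partners and targets from blood cell studies had a peak in 8 of 15 genes. MYC reached 45.5, NOTCH1 25.1 and SPEN, a paralog of RBM15, 23.2 with 11 peaks. Their mean of 3.88 peaks per gene (SD 3.4 over genes) was 2.24 times the random mean (two-sided permutation p = 0.00824, adjusted p = 0.0412), and their median score was 2.45 times the random median (two-sided permutation p = 0.0312, adjusted p = 0.0605). Against genes with the same number of peaks, the score ratio was 1.36 (permutation adjusted p = 0.388), and with a gene's scores summed it was 4.78 (permutation adjusted p = 0.0072). The call on peaks per gene was lost when peaks within 50 bases of each other were merged (2.08-fold, permutation adjusted p = 0.0561) and in 3 other settings given with the processing alternatives.

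Cell cycle genes had a peak in 20 of 31 cases, led by the proliferation marker gene MKI67 (74.9, 13 peaks), MYC (45.5, also in the list of RBM15 partners), the topoisomerase gene TOP2A (34.8) and RB1 (34.5), whose interval was also listed under the pseudogene PCNPP5 on the opposite strand (11.21). Neither their score, 1.78 times the random median (two-sided permutation p = 0.0363, adjusted p = 0.0605), nor their 2.7 peaks per gene, 1.56 times the random mean (two-sided permutation p = 0.021, adjusted p = 0.0699), passed after correction. Apoptosis genes had a peak in 9 of 23 cases, with the survivin gene BIRC5 at 66.3, BIRC2 at 18.2 and FADD at 15.9, and differed from random sets in neither measure (scores 1.49-fold, adjusted p = 0.367; peaks per gene 0.64-fold, adjusted p = 0.184; two-sided permutation tests).

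Of 20 genes of androgen signalling and the prostate, 8 had a peak. NDRG1 (33.1), the glucocorticoid and androgen response gene FKBP5 (26.4), TRIM36 (24.9, 5 peaks) and the pioneer factor gene FOXA1 (18.6) had the strongest, and KLK3, which encodes prostate-specific antigen, had no peak. Scores were 1.76 times and peaks per gene 1.23 times those of random sets, and neither passed (adjusted p = 0.21 and 0.411, two-sided permutation tests). Among peaks at or above the median score, the ratio for peaks per gene turned to 0.83 (permutation adjusted p = 0.784).

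Long noncoding RNAs had a peak in 12 of 20 cases, with MALAT1, an abundant nuclear RNA, at 97.6 with 9 peaks, and the small nucleolar RNA host genes SNHG1 at 65.2 and GAS5 at 58.5, ahead of OIP5-AS1 at 20.03. NEAT1, KCNQ1OT1, HOTAIR and PCA3 had no peak, and CCAT1 matched no gene identifier. The list did not pass on score (1.65-fold, adjusted p = 0.206) or on peaks per gene (1.35-fold, adjusted p = 0.203; two-sided permutation tests). Of 18 small structured RNAs, SNORD3A, the U3 small nucleolar RNA, had a peak at 30.2 and RN7SK, the 7SK RNA, a peak at 6.66, and the other 16 had none.

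Among 13 hematopoietic markers, HBA1 (10.9) and ITGAM (6.41) had a peak, and HBA1 has a near-identical copy. Among 13 stromal and endothelial markers, VWF had a peak at 5.26. The ITGAM and VWF peaks were short, at 19 and 21 bases. These lists, the structured RNAs and the mitochondrial genes had fewer than 3 genes with a peak each and were not tested, which left 10 lists for the correction.

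**Figure D3:**
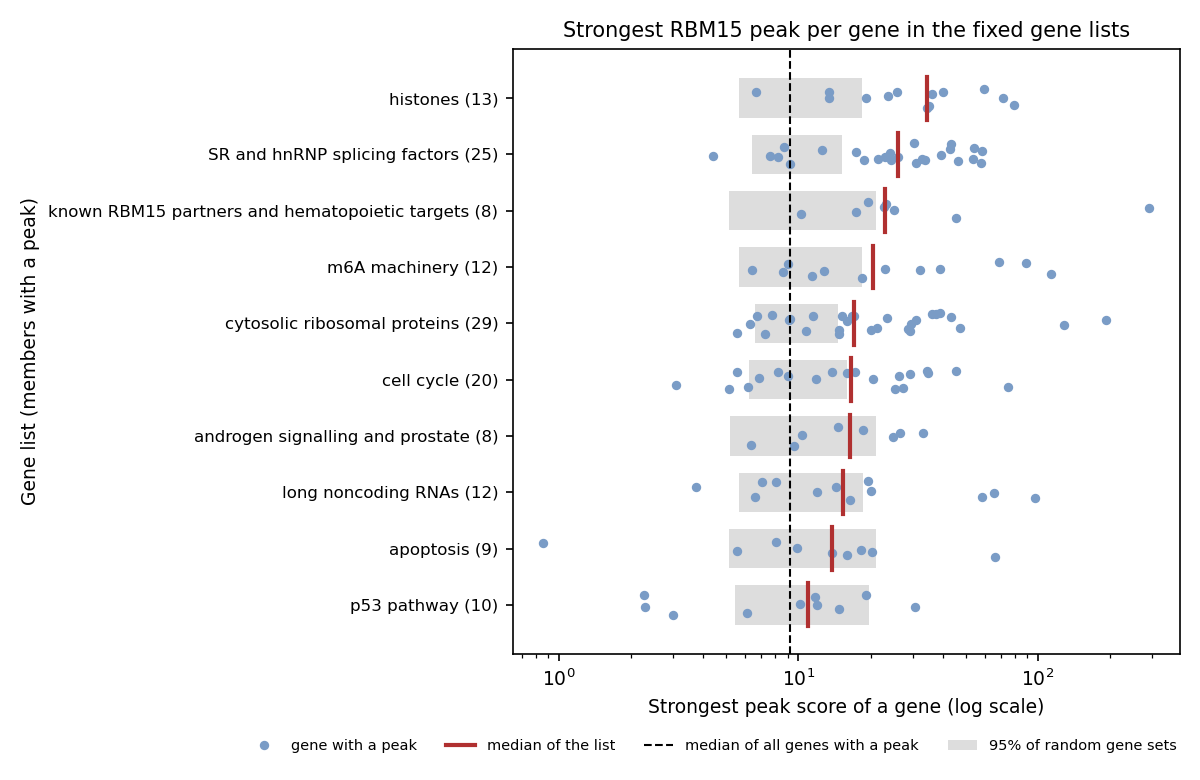
Strongest peak score of each gene with a peak (points, logarithmic axis) in the 10 tested gene lists, with the number of such genes in brackets, the list's median (red line), the central 95% of medians of random gene sets of the same size (grey bars) and the median of all genes with a peak (dashed line, 9.25). The medians of histone genes (34.48) and splicing factors (26.09) lie farthest to the right, and that of p53 pathway genes (10.91) lies inside its grey bar.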

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

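The settings with protein-coding genes as background, matching on mature length, and intervals listed under several genes or on both strands left out or collapsed were chosen after the data were seen. No paired analysis was possible because the peak list has no value per library; for the same reason CLIP against input per peak, its replicate block and leaving out each library were not run, and neither were the alternatives that need a p-value, another strength measure, coverage, or an hg19 annotation or genome. Of the 69 alternative values for list strength, 61 kept their direction and side of the threshold, and of the 59 for peaks per gene, 52 did. Keeping peaks at or above the median score left 8042 peaks and 5188 genes, and at least 2 peaks left 3399 genes, by construction. Among peaks at or above the median score, the correlation of score and length fell to 0.18, which the narrowed range of the score can bring about by itself. With a gene's scores summed, strength was 0.95-fold in the p53 list, which reversed its direction, and passed the threshold for the m6A machinery (2.78-fold), the cell cycle (2.13-fold) and RBM15 partners (4.78-fold); matched on the number of peaks, these lists were 1.47-fold, 1.32-fold and 1.36-fold and did not pass (permutation adjusted p = 0.326, 0.328 and 0.388). The m6A list also passed (2.27-fold) without intervals listed on both strands. Matched on the number of peaks, the strength of splicing factors (1.57-fold) and ribosomal proteins (1.36-fold) no longer passed, and against protein-coding genes that of ribosomal proteins (1.65-fold) did not. For peaks per gene, the androgen and prostate list reversed to 0.83-fold among peaks at or above the median score, and ribosomal proteins (1.43-fold) and the cell cycle (1.58-fold) passed when matched on mature length. RBM15 partners did not pass with peaks merged (2.08-fold), with peaks at or above the median score (1.53-fold), against protein-coding genes (2.05-fold) or matched on mature length (1.76-fold). Except where stated as by construction, the cause was not tested. Depth per library is unknown, so its effect on which genes have a peak could not be examined.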

Other observations

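The shares of genes with a peak and the intronic lengths below were examined after the data were seen, as were the families, which were picked for their shares; among the weighed patterns, the test of paired scores and the set of genes in both tests of the third pattern were chosen after values were seen, and the other tests were not.

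Among the fixed lists, histones (13 of 22 genes with a peak, mean of 3.4 in protein-coding sets matched on mature length), ribosomal proteins (29 of 33, 10.5), splicing factors (25 of 29, 12.6) and cell cycle genes (20 of 31, 10.7) had more genes with a peak than matched sets, and stromal markers had fewer (1 of 13, 5.7). In two-sided permutation tests adjusted over 12 lists, adjusted p was 0.0012 for ribosomal proteins and splicing factors, the smallest that 10000 draws gave here, 0.0016 for histones, 0.003 for the cell cycle and 0.024 for stromal markers. The other 7 lists did not pass, among them hematopoietic markers (2 of 13, 3.4, permutation adjusted p = 0.805), the m6A machinery (12 of 21, 9.1, permutation adjusted p = 0.523) and the p53 pathway (10 of 30, 10.2, permutation adjusted p = 1.0). The 16 families that follow were not tested, because their shares led to their choice; each count is followed by the central 95% of matched sets. Counts lay above that range for translation initiation factors (40 of 56, 14 to 28), with EIF3C (118.1) and its near-identical copy EIF3CL (87.4) at the top, aminoacyl-tRNA synthetases (13 of 17, 3 to 11), led by MARS1 (77.1), and SF3 splicing factor subunits (8 of 9, 1 to 6), led by SF3B3 (119.6). They also did for CHD remodelers (10 of 10, 2 to 8), SMARC remodelers (10 of 13, 3 to 9), chaperonin CCT subunits (7 of 9, 0 to 6), proteasome subunits (23 of 44, 9 to 20) and mitochondrial ribosomal proteins (29 of 78, 13 to 28). The strongest intervals of EIF3C and MARS1 were also listed on the opposite strand, under PLA2G10DP (146.45) and DDIT3 (51.88). Counts lay within the range for histone lysine methyltransferases and demethylases (17 of 28, 8 to 18), DEAD and DEAH box helicases (30 of 55, 16 to 30), kinesins (21 of 40, 11 to 23) and bitter taste receptors (3 of 24, 1 to 7). They lay below it for olfactory receptors (3 of 386, 66 to 95), keratin-associated proteins (1 of 94, 6 to 18), zinc finger genes named ZNF (171 of 514, 175 to 216) and solute carriers (120 of 374, 121 to 156). Expression in these cells was not used, so these shares do not separate binding from expression.

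Among small RNA copies, 51 of 293 annotated 7SK pseudogenes had a peak (median score 7.2), against 3 of 677 7SL pseudogenes and 0 of 1271 U6 pseudogenes, and 4 of 6 copies of the U3 RNA SNORD3 had a peak. The 100 protein-coding genes with the strongest peaks had a median intronic length of 115.7 kb, against 34.6 kb in the others (ratio 3.35, bootstrap 95% interval 2.83 to 4.25), and among genes with 1 peak the ratio was 3.01 (1.92 to 4.04). The measure first meant to be used for this, the rank correlation of score and intronic length among genes with 1 peak, was -0.05 (-0.09 to -0.02) across 3841 genes, of the opposite sign.

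The first pattern was that 740 intervals stood with the same start and end under genes of both strands. Whether these were separate peaks that happen to lie together was examined by comparing their scores with random pairings. The higher score of a pair exceeded the lower by a median of 24.1%, against 96.9% to 120.3% in the central 95% of 10000 random pairings. The random pairings were not matched on length. Paired intervals have the same length, and longer peaks scored higher (Spearman's rho 0.56 across peaks). Scores of separate peaks at the same place could thus also be alike, and this test does not decide. The other explanation, that peak calls did not separate the strands, was tested on peaks between the outermost peaks of an opposite-strand gene. Of these, 82.0% overlapped a peak of that gene, against 84.3% for a same-strand gene. The list may therefore hold peaks without strand information, and a peak of an antisense gene such as KIZ-AS1 could belong to its partner; no biological explanation was tested.

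The second pattern was the presence of 821 peaks in processed pseudogenes. Among pseudogenes named after a protein-coding parent, the parent also had a peak in 92.0% of those with a peak and in 64.5% of those without, a difference of 27.6 percentage points (two-sided permutation p = 0.0002, the smallest that 10000 permutations can give), with KRT8 (18 of 49 pseudogenes), RPL23A (17 of 84), EEF1A1 (13 of 37) and NPM1 (13 of 43) most often seen. This is consistent with reads of the parent placed on its copies, although parents with a peak may also be highly expressed, which was not controlled. An overlapping gene on the same strand is argued against as the main source, since 15.8% of these peaks (exact 95% interval 13.4 to 18.5) overlapped a peak of another gene there; on either strand 36.3% (33.0 to 39.7) did, which leaves reads of an overlapping gene open for part of them. No biological explanation was tested.

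The third pattern was the absence of a peak in FAS, TP53INP1, SESN2 and FTO. Whether their mature transcripts are too short could not be decided. The length used joins the exons of all annotated transcripts of a gene, so it can exceed that of any single transcript. The median of the 4 genes, 4964.5 bases, lay at percentile 44.1 of protein-coding genes with a peak. SESN2 (3453) and FAS (4253) lay below and TP53INP1 (5676) and FTO (21379) above 5432 bases, the median of protein-coding genes with a peak. Of 10000 random sets of 4 protein-coding genes matched on mature length, 13.3% had no peak in any gene. The 4 genes were chosen as a set after their lack of a peak was seen. The random sets came from all annotated protein-coding genes, whether expressed in these cells or not. The test therefore cannot say how often expressed genes of like length lack a peak, and no conclusion is drawn from it. Peaks below the authors' threshold and low expression stay open and were not tested.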
